A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

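RNA polymerase II (Pol II) occupancy in budding yeast was measured by chromatin immunoprecipitation and sequencing with an antibody against the C-terminal domain of the polymerase. The series held 12 libraries. Cells carried wild-type PCF11 (WT), the pcf11-13 allele (Pcf11-13) or an allele titled Pcf11-DNL, each on a LEU2 plasmid in a strain whose chromosomal PCF11 was deleted with TRP1. Each of the 3 genotypes had 2 Pol II libraries and 2 input libraries of unprecipitated DNA, and groups and replicate numbers were taken from the sample titles. The series text names the other allele Pcf11-dQN where the titles have Pcf11-DNL, and the title's name is used here.

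The deposited values are read coverage, a signal that is not scaled to library depth. The submitters' processing notes name Trimmomatic 0.38, BWA 0.7.17-r1188, deepTools 3.1.2 and the sacCer3 build, without giving the role or order of each. How coverage was averaged over a gene is not stated. The values are not whole numbers. Multiplied by gene length they were whole in all 12 libraries, within 0.0006 per base of length, for 139 of 141 short genes (at most 300 bp) on the Watson strand and for 51 of 150 on the Crick strand. With the length shifted by 7 bases, 0 of 291 were whole. Among longer genes, 104 fitted a short stretch of at most 300 bp, 33 of them ribosomal protein genes, so their values cover part of the gene only. The number of reads behind a value is therefore unknown, and no counting interval is given.

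The files hold 6650 genes, of which 5976 matched a locus tag in the RefSeq gene table of the same assembly, and 674 did not and have no coordinates here. The files hold 0 rows for small nucleolar RNA (snoRNA) genes, so that fixed list was not used here. The libraries do not separate strands. Near-identical copies such as the CUP1 genes cannot be told apart.

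A count test on the deposited values had been chosen before the data were examined, with limma on log2 values as its replacement if the files held no counts. The replacement was used. Coverage was divided by trimmed-mean (TMM) scaling factors, computed without weights after trimming 30 percent of log ratios and 5 percent of mean levels. A pseudocount of 1 was added before the log2 transformation. Genes with a coverage of at least 10 in at least 2 libraries were kept; this coverage minimum replaced the count filter of the original plan and was set after the unit was known. limma 3.58.1 in R 4.3.3 with a mean-variance trend was fitted to all 6 libraries of an assay, so that the 3 genotypes shared 1 estimate of the spread. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of genes are from this limma fit unless another setting is named. Folds are 2 to the power of the log2 change, and scaled coverage is given as mean ± SD of 2 libraries.

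Gene lists were written before the data were examined, and 24 with at least 5 measured members were tested with limma's camera, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 24 lists. The test was repeated with a correlation estimated for each list. The lists covered ribosomal protein, ribosome biogenesis, stress response induced, heat shock factor targets, glucose-repressed, tricarboxylic acid cycle and respiration, glycolysis and fermentation, phosphate regulon, amino acid biosynthesis, sulfur and methionine, purine and one-carbon, iron regulon, cell wall, pheromone response, a-cell specific, meiosis and sporulation, histone, proteasome, cleavage, polyadenylation and termination factors, Nrd1-attenuated, strain marker, downstream of snoRNA, tandem downstream and subtelomeric genes. The alpha-cell specific list has 4 members and was described only. Downstream of snoRNA means the next gene within 1000 bp on the same strand, tandem downstream the next gene within 500 bp on the same strand, and subtelomeric within 20000 bp of a chromosome end.

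The genes named were set by a rule fixed in advance. It took up to 8 named genes with the largest rises and up to 8 with the largest falls among called genes whose mutant libraries both lay beyond both WT libraries. It added up to 4 called genes per called list of at most 200 members, up to 5 rises and 5 falls between the mutants, the 10 named genes of highest WT enrichment, and PCF11, LEU2, TRP1, URA3, HIS3 and ADE2. With fewer than 5 called genes, the 5 with the smallest p were taken. A gene that the rule takes is not reported here. Genes outside it were chosen after their values were seen, as is said where they appear.

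On data simulated from the real means and spread for 6642 genes, the Pcf11-13 comparison recovered 45.3% of genes changed 1.3-fold, 84.1% of those changed 1.5-fold and 94% of those changed 2-fold, with 11 false calls. The Pcf11-DNL comparison recovered 43.1%, 87.3% and 95.3%, with 5 false calls. Of its 28 recovered genes changed 1.3-fold, 27 had the simulated sign, so the requirement of a matching sign for every gene was relaxed. The noise was drawn independently for each gene and library. Genes in the real libraries deviated together, so these rates and false calls may not hold for the real data.

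Alternatives fixed in advance were other scalings, filters, the matched input as an offset, a 12-library model, a replicate block, the 4 compared libraries alone and each library left out. Quantile normalization, a pseudocount of 5, leaving out the 2 libraries of narrow coverage range, a crossed block, and list tests under library totals and under meiosis gene scaling were added after the data were seen. The planned count tests were not run. For the closing section, 11 tests of explanations were made, 2 of them written before the values they measure were seen and 9 after, along with 10 comparisons of gene sets with random sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.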

Results

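Pol II occupancy was measured in yeast whose only PCF11 gene was a plasmid copy. Pcf11 is an essential subunit of the factor that cleaves pre-mRNA 3' ends, and it takes part in Pol II termination. The groups WT, Pcf11-13 and Pcf11-DNL had 2 Pol II and 2 input libraries each. Mean Pol II coverage per gene was 140.1 and 161.8 in WT, 185.9 and 300.7 in Pcf11-13, and 158.2 and 206.8 in Pcf11-DNL, for replicates 1 and 2. Mean input coverage was 157.7 and 175.2, 169.6 and 150.2, and 189.1 and 132.3 in the same order. Across genes, which are not independent replicates, the log2 Pol II values of replicates had r = 0.972 in WT, 0.994 in Pcf11-13 and 0.988 in Pcf11-DNL. WT replicate 1 and Pcf11-DNL replicate 2 had a narrow range of coverage over genes, with an SD of 0.926 and 0.916 on the log2 scale. The other Pol II libraries had 1.203 (WT replicate 2), 1.15 and 1.141 (Pcf11-13), and 1.088 (Pcf11-DNL replicate 1).

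In WT cells Pol II was densest over housekeeping genes of growth. CCW12, a cell wall mannoprotein gene (YLR110C, chromosome XII, 369697 to 370098), had a Pol II to input ratio 25.7-fold above the median gene (log2 4.68 ± 0.50, SD, n = 2). The glycolytic and fermentation genes PDC1, TDH3 and ENO2 reached 25.3-fold, 24.9-fold and 19.1-fold. The translation genes HYP2, RPL8A, RPL10, TEF1 and RPS31 reached 23.4-fold, 21.5-fold, 20.3-fold, 19.8-fold and 19.1-fold, and the proton pump gene PMA1 reached 20.4-fold. Glycolysis and fermentation genes had a median of 11.1-fold, histone genes 7.93-fold, ribosomal protein genes 7.82-fold and the 4 alpha-cell specific genes 4.66-fold, in a strain of mating type alpha. Genes silent in such cells lay below the median gene, with 0.398-fold for meiosis and sporulation genes and 0.352-fold for a-cell specific genes. Of 6645 genes, 870 (13.1%) were more than 2-fold above the median gene. This description has no test.

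The comparison of Pcf11-13 with WT asks where Pol II over genes differs between these strains. Their input DNA differed at 17 of 6643 genes, against 0 between Pcf11-DNL and WT. A Pol II change in Pcf11-13 may therefore come from the allele or from another difference of the strain. Before input was taken into account, Pol II rose most over PCF11 itself (YDR228C, chromosome IV, 921926 to 923806), from a scaled coverage of 161 ± 9.95 in WT to 803 ± 62.5 in Pcf11-13 (SD, n = 2), 4.95-fold (log2 2.31, SE 0.10, adjusted p = 2.1e-05). Its input also rose, by 0.56 on the log2 scale, and the Pol II change less the input change was 1.75, below the 1.87 of YMR194C-A, which had the next largest rise in Pol II (3.91-fold, log2 1.97) and is named for this comparison after its values were seen. PAM16, which encodes a subunit of the mitochondrial import motor (YJL104W, chromosome X, 227327 to 227776), rose from 181 ± 7.28 to 488 ± 0.627, 2.68-fold (log2 1.42, SE 0.09, adjusted p = 2.0e-04). HIS4 of histidine synthesis (YCL030C, chromosome III, 65934 to 68333) rose from 166 ± 4.91 to 339 ± 4.71, 2.03-fold (log2 1.02, SE 0.08, adjusted p = 6.5e-04). VMA9, a subunit gene of the vacuolar proton pump (YCL005W-A), rose 2.44-fold (log2 1.29, SE 0.08, adjusted p = 2.0e-04), although its value fitted a stretch of 11 of its 395 bp only. Its input change was 0.20 (SE 0.07, not called), leaving 1.08. Pol II fell over the glucose transporter gene HXT1 (YHR094C, chromosome VIII, 290913 to 292625), from 308 ± 20.2 to 125 ± 5.04, a log2 change of -1.30 (SE 0.10, adjusted p = 6.2e-04).

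**Figure D1:**
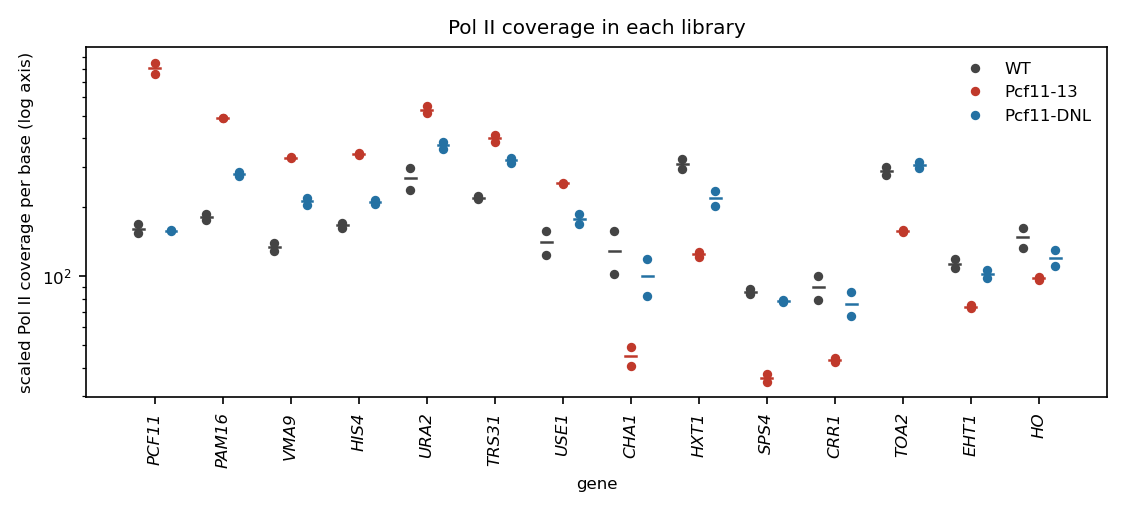
Scaled Pol II coverage per base on a log axis for 14 genes, with 1 point per library and a line at the mean of 2 libraries. For PCF11 the Pcf11-13 mean is 803 and the WT mean 161, and for HXT1 125 and 308.

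In total 76 of 6642 genes passed, 66 higher and 10 lower, with 839 at an unadjusted p under 0.05. In all 76 the mutant libraries lay beyond both WT libraries, which held for 40.1% of all genes against 33.3% by chance. Among the other large rises were URA2, of pyrimidine synthesis (log2 0.99, adjusted p = 0.011), and TRS31 and USE1, of vesicle traffic (0.85, adjusted p = 0.0044, and 0.85, adjusted p = 0.014). The falls included CHA1, of serine and threonine breakdown (log2 -1.48, adjusted p = 0.019), and the sporulation genes SPS4 (-1.22, adjusted p = 0.0011) and CRR1 (-1.03, adjusted p = 0.019). EHT1 (-0.61, adjusted p = 0.011), the mating-type endonuclease gene HO (-0.58, adjusted p = 0.049) and the copper transporter gene CCC2 (-0.47, adjusted p = 0.047) fell as well. TOA2, a TFIIA subunit gene, fell in Pol II (-0.86, adjusted p = 0.003) and in input (-0.75), leaving -0.11. Of the plasmid and marker genes, ADE2 (0.25), HIS3 (0.32), LEU2 (-0.08), TRP1 (0.24) and URA3 (-0.18) did not pass. Input rose by 0.44 at LEU2 and 0.62 at TRP1, leaving -0.52 and -0.38. The number of calls ranged from 8 to 1213 with 1 library left out: 8 without Pcf11-13 replicate 2, 9 without Pcf11-13 replicate 1, 432 without WT replicate 1 and 1213 without WT replicate 2. It was 19 when libraries were scaled on meiosis and sporulation genes and 630 without both libraries of narrow range.

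Genes downstream of snoRNA genes, whose transcripts end through a pathway that does not need cleavage, rose as a group in Pcf11-13. Of 26 members, 7 rose and 0 fell over all genes, and 8 and 0 adjusted over the list alone. The median log2 change was 0.10 and 20 members were higher (camera adjusted p = 5.7e-07, and adjusted p = 0.31 with an estimated correlation). YDR042C, an uncharacterised gene, rose 2.36-fold (log2 1.24, SE 0.11, adjusted p = 0.0012), HEM4 of heme synthesis 1.72-fold (0.79, SE 0.08, adjusted p = 0.003) and CTO1 1.6-fold (0.68, SE 0.07, adjusted p = 0.0044). SEN2, TRS31, USE1 and PDX3 were the other 4, SEN2 and PDX3 being named after their values were seen. The share called higher was 26.9% on the list and 0.892% among the 6616 other genes (Fisher's exact test, two-sided, odds ratio 40.8, 95% interval 13.9 to 106, p = 3.9e-09, adjusted p = 1.6e-08 over 4 lists). For tandem downstream genes, 14 of 1823 were called higher against 52 of 4819 others (Fisher's exact test, p = 0.33, adjusted p = 0.33). Fisher's exact test was run, here and below, on these 4 lists only, and its adjustment covers those alone. No rule for choosing them is given, so the adjusted values may understate the search. The test takes genes as independent, so its p-values and interval do not cover the spread between cultures.

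**Figure D2:**
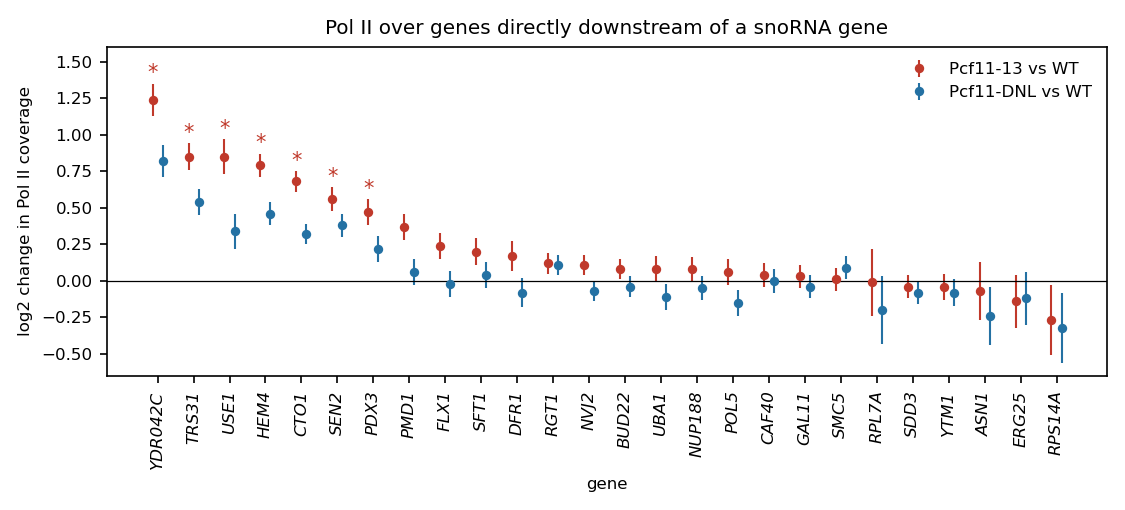
Log2 change in Pol II coverage, with its standard error, of the 26 genes downstream of a snoRNA gene in both mutants against WT, with an asterisk at an adjusted p under 0.05 in Pcf11-13. YDR042C has the largest change, 1.24 in Pcf11-13 and 0.82 in Pcf11-DNL.

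The Nrd1-attenuated, amino acid biosynthesis, purine and one-carbon, cell wall, strain marker and proteasome lists were also called higher in Pcf11-13. The 10 Nrd1-attenuated genes, at which early termination limits transcription, had a median of 0.37, with 10 higher, 3 called (PCF11, URA2 and ADE12, the last at log2 0.50, adjusted p = 0.043) and 6 adjusted over the list alone (camera adjusted p = 6.7e-09, and adjusted p = 0.31 with an estimated correlation). Fisher's exact test gave p = 1.1e-04 (adjusted p = 2.2e-04) for its called members. PCF11, the plasmid gene whose input also rose, counts in each of these values. Of the 9 other members, 9 were higher and 2 were called. Amino acid biosynthesis genes had a median of 0.26, with 26 of 30 higher, 3 called (HIS4, ARG4 at 0.62 and ARG1 at 0.61) and 14 adjusted over the list alone (camera adjusted p = 2.1e-12, and adjusted p = 0.39 with an estimated correlation; Fisher's exact test p = 0.0031, adjusted p = 0.0041). Purine and one-carbon genes had a median of 0.26, with 12 of 12 higher, 1 called and 3 adjusted over the list alone (camera adjusted p = 6.7e-06, and adjusted p = 0.31 with an estimated correlation). Cell wall genes had a median of 0.26 (adjusted p = 9.9e-04, and adjusted p = 0.56 with an estimated correlation), with 0 called and 2 adjusted over the list alone. Strain markers had 0.24 (adjusted p = 0.0045, and adjusted p = 0.39 with an estimated correlation), with 1 called and 3 adjusted over the list alone, and were not called with input subtracted. Proteasome genes had 0.10 with 31 of 31 higher and 0 called (adjusted p = 6.7e-06, and adjusted p = 0.86 with an estimated correlation), and were not called after quantile normalization (adjusted p = 0.52).

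Tricarboxylic acid cycle and respiration genes were lower as a group, with a median of -0.18 and 38 of 46 lower (camera adjusted p = 1.0e-05, and adjusted p = 0.98 with an estimated correlation). Iron regulon genes had a median of -0.17 with 13 of 15 lower (adjusted p = 2.1e-04, and adjusted p = 0.31 with an estimated correlation), and ribosome biogenesis genes -0.05 with 101 of 129 lower (adjusted p = 0.0076, and adjusted p = 0.98 with an estimated correlation). In these 3 lists 0 members were called over all genes, and adjusted over the list alone 1 iron regulon gene was lower. The other 14 lists were not called, with medians from -0.21 to 0.06 and a smallest adjusted p of 0.059. Scaling on meiosis and sporulation genes moved the median of all genes to 0.15, and the medians of these 3 lists to -0.02, -0.01 and 0.11. Without WT replicate 2 the direction for ribosome biogenesis genes turned, with a median of -0.00. No list kept its call with an estimated correlation.

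**Figure D3:**
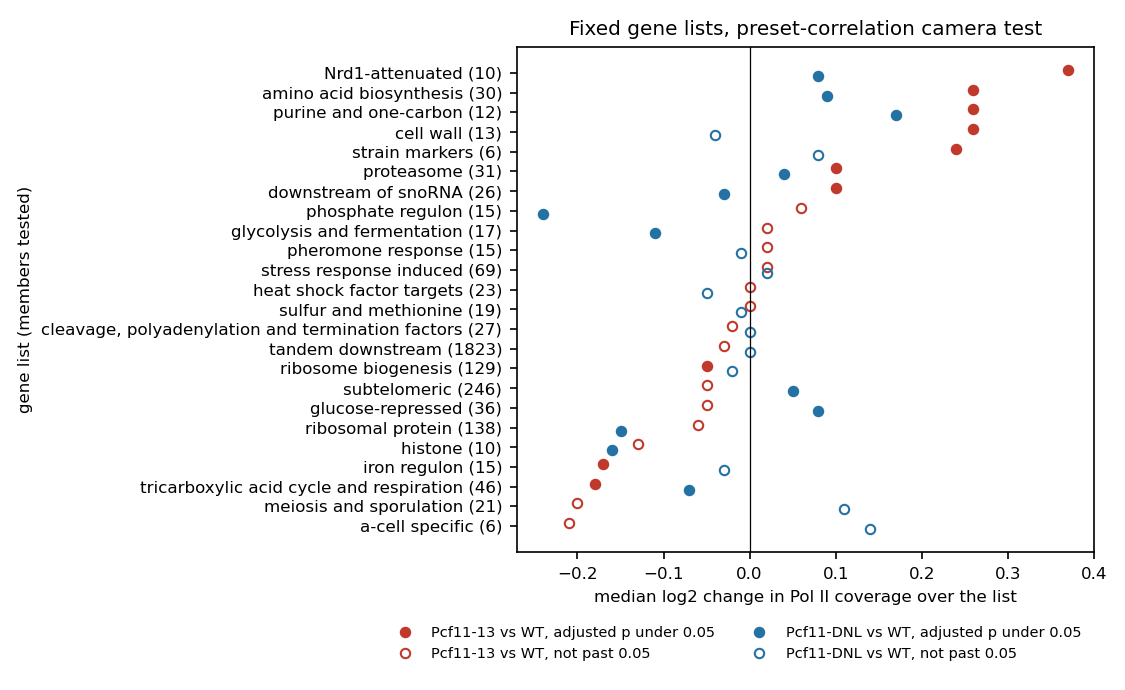
Median log2 change in Pol II coverage of 24 gene lists in each mutant against WT, filled where the camera test with the preset correlation gave an adjusted p under 0.05. Nrd1-attenuated genes have the highest median in Pcf11-13, 0.37, and phosphate regulon genes the lowest in Pcf11-DNL, -0.24; scaling on meiosis and sporulation genes moves the median of all genes in Pcf11-13 to 0.15 and that of ribosome biogenesis genes to 0.11.

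The comparison of Pcf11-DNL with WT asks the same of the other allele. A single gene passed, YMR194C-A, which has no coordinates here and rose from 178 ± 2.64 to 407 ± 42.1 (SD, n = 2), 2.27-fold (log2 1.19, SE 0.11, adjusted p = 0.016). It was called in Pcf11-13 too, at 697 ± 7.64 (log2 1.97, SE 0.11, adjusted p = 1.2e-04). By its systematic name it lies near RPL36A (YMR194W) and CMC4 (YMR194C-B), the 5' and 3' side neighbours of the snoRNA gene SNR11. Without coordinates it was in no gene set next to snoRNA genes. RPL36A and CMC4, named after their values were seen, were not called in either mutant. Pol II over PCF11 was 158 ± 0.294 against 161 ± 9.95 (log2 -0.03, adjusted p = 1). The next smallest p-values did not pass: YDR042C at 0.82 (adjusted p = 0.088), VMA9 at 0.65 (adjusted p = 0.088), PAM16 at 0.62 (adjusted p = 0.12) and HEM4 at 0.46 (adjusted p = 0.32). The markers ADE2 (0.16), HIS3 (0.11), LEU2 (0.10), TRP1 (-0.01) and URA3 (0.05) did not pass either. Of 6642 genes, 107 had an unadjusted p under 0.05. The number of calls was 401 without WT replicate 1, 28 without WT replicate 2, 0 without either Pcf11-13 library and 110 without both libraries of narrow range.

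Ribosomal protein genes were lower as a group in Pcf11-DNL, with a median of -0.15 and 134 of 138 lower (camera adjusted p = 1.6e-16, and adjusted p = 0.80 with an estimated correlation, as for the 11 other lists called). Phosphate regulon genes had -0.24 with 15 of 15 lower (adjusted p = 4.5e-06), glycolysis and fermentation genes -0.11 with 17 of 17 lower (adjusted p = 0.0025), histone genes -0.16 (adjusted p = 0.013) and tricarboxylic acid cycle and respiration genes -0.07 (adjusted p = 3.4e-04). The lists that were higher were purine and one-carbon at 0.17 (adjusted p = 1.3e-04), amino acid biosynthesis at 0.09 (adjusted p = 1.2e-06), glucose-repressed at 0.08 (adjusted p = 0.013), Nrd1-attenuated at 0.08 (adjusted p = 0.018), subtelomeric at 0.05 (adjusted p = 0.013) and proteasome at 0.04 (adjusted p = 0.015). Genes downstream of snoRNA genes had a median of -0.03 but a mean of 0.07 and a call in the higher direction (adjusted p = 0.026), with 5 higher adjusted over the list alone. Over all genes, 0 members of these 12 lists were called. Settings that bear on the narrow coverage range of WT replicate 1 and Pcf11-DNL replicate 2 disagree. After quantile normalization ribosomal protein genes had a median of -0.01 (adjusted p = 0.29), and 6 of the 12 lists were still called, while without both libraries they had -0.18 (adjusted p = 3.6e-21), and 8 of the 12 were. Without WT replicate 2 the direction turned for 7 of these 12 lists, with medians of 0.04 (ribosomal protein), 0.09 (glycolysis and fermentation), 0.05 (phosphate regulon), 0.04 (histone), 0.05 (tricarboxylic acid cycle and respiration), -0.11 (glucose-repressed) and -0.07 (subtelomeric). Without Pcf11-DNL replicate 2 it turned for histone (0.03), glucose-repressed (-0.06), subtelomeric (-0.06) and ribosomal protein genes (-0.00), and the proteasome median was -0.02 without WT replicate 1 or Pcf11-DNL replicate 1. The test of genes downstream of snoRNA genes turned without WT replicate 1 (median -0.07). The other 12 lists were not called, with medians from -0.05 to 0.14 and a smallest adjusted p of 0.08.

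The mutants were also compared with each other. Their input differed at 17 genes, so a difference may come from the alleles or from other differences of the strains. PCF11 was lower in Pcf11-DNL than in Pcf11-13 (log2 -2.34, SE 0.10, adjusted p = 1.9e-05), and so were PAM16 (-0.80, adjusted p = 0.017), HIS4 (-0.69, adjusted p = 0.02), VMA9 (-0.63, adjusted p = 0.028) and MIN3 (-0.53, adjusted p = 0.049). SPS4 (1.09, adjusted p = 0.0066), TOA2 (0.95, adjusted p = 0.0066) and HXT1 (0.80, adjusted p = 0.021) were higher. Input differed by 0.88 at TOA2, leaving 0.07, and by -0.57 at PCF11, leaving -1.77. In total 11 of 6642 genes passed, 4 higher and 7 lower, with 731 at an unadjusted p under 0.05. The balance depends on the scaling, with 21 higher and 8 lower when libraries were scaled on meiosis and sporulation genes and 20 higher and 99 lower with library totals. Of 24 lists 16 were called, and 0 with an estimated correlation (smallest adjusted p = 0.46 with an estimated correlation). The number of calls ranged from 1, without either Pcf11-13 library, to 679, without WT replicate 2, and was 671 without WT replicate 1.

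Of the 76 genes called in Pcf11-13, 71 (93.4%) had the same sign in Pcf11-DNL, and the median ratio of the changes was 0.36. All 76 had a smaller change in Pcf11-DNL, which their choice by the Pcf11-13 test builds in (100% in the simulations). In 50 simulations that kept the Pcf11-13 effects and left Pcf11-DNL unchanged against the same WT libraries, the share was 54.1% (highest 67.8%) and the ratio 0.01 (highest 0.05). The overlap of calls was 1 gene, against 0.00994 for independent lists of higher genes and up to 2 in those simulations, so it is not beyond what shared controls give. Across all 6642 genes, which are not independent, the changes had r = 0.02 and rho = 0.12, with 0.48 in 100 simulations without any effect (highest 0.78). The covariance was 0.0005 against 0.0484 simulated, a difference of -0.0479. Across all genes the changes thus showed no excess over the simulations. For the called genes the simulations hold the same WT libraries. The controls were not split, since each part would hold 1 WT library, so part of the excess at called genes may still come from sharing them. The correlation was 0.85 without WT replicate 2, 0.49 without WT replicate 1, 0.51 without Pcf11-DNL replicate 2 and -0.24 without Pcf11-DNL replicate 1. No simulated value is given for these settings.

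Input DNA differed between Pcf11-13 and WT at PCF11, LEU2 and TRP1, and not at the markers URA3 (log2 -0.01), HIS3 (-0.03) and ADE2 (0.00), each with an adjusted p = 1. PCF11 input was 2.19 times the median gene in Pcf11-13, 1.49 in WT and 1.48 in Pcf11-DNL. LEU2 stood at 4.07, 2.99 and 3.3, and TRP1 at 1.57, 1.02 and 1.02. TOA2 and MPE1, neighbours on chromosome XI, were at 1.01 and 1.04 in Pcf11-13 against 1.7 and 1.42 in WT. In Pcf11-DNL they were at 1.86 and 1.44. FBA1, next to MPE1, was at 1.13 in Pcf11-13, 1.52 in WT and 1.57 in Pcf11-DNL (limma adjusted p = 0.0051 for Pcf11-13 against WT). At these genes Pcf11-13 thus lay nearest to the median gene, and WT and Pcf11-DNL lay above it. The copper-binding protein gene CUP1-1, a repeated locus, was at 4.6 against 7.66 and its neighbour RSC30 at 2.31 against 3.48. MPE1, FBA1, CUP1-1 and RSC30 were chosen after their values were seen. In total 17 of 6643 genes passed, 8 higher and 9 lower, with 384 at an unadjusted p under 0.05. Between Pcf11-DNL and WT limma called 0 genes, with 232 at an unadjusted p under 0.05. Chromosome XIII lay 9.22% above WT in Pcf11-13 replicate 1 and 1.93% in replicate 2, and chromosome XII was at -0.024 and -0.020 in Pcf11-13 and at -0.016 in Pcf11-DNL replicate 1 on the log2 scale. The input medians of the chromosomes other than XII and XIII were within 0.013 of WT.

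**Figure D4:**
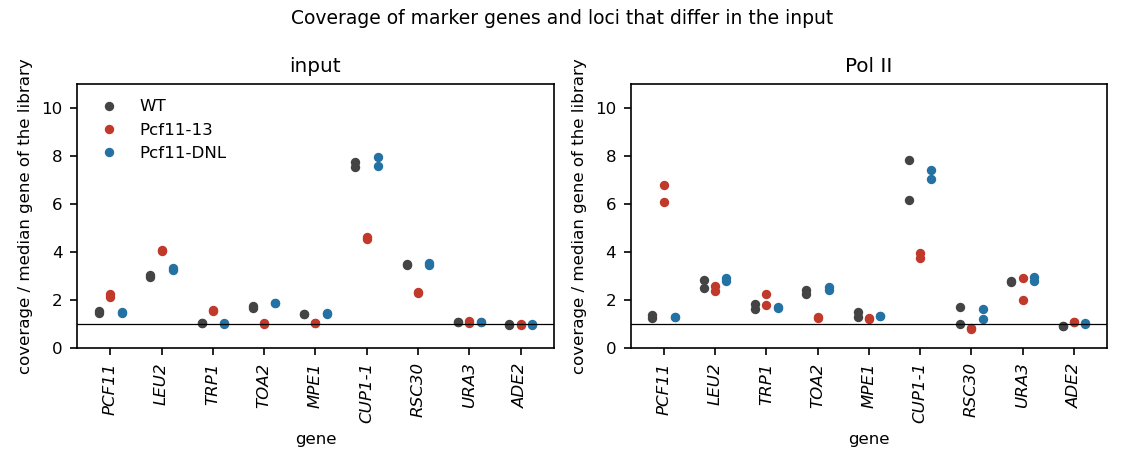
Coverage over the library's median gene in input and Pol II libraries at 9 loci, with 1 point per library and a line at 1. PCF11 input is 2.19 in Pcf11-13 and 1.49 in WT, and TOA2 input 1.01 and 1.7.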

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

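Of the 11 tests used here and below to weigh explanations, those of position next to any short noncoding gene and of distance were set before their values were seen, and the other 9 were chosen only after the results were seen. For PCF11 attenuation and the Pcf11-DNL lists a second rule was tried once values were known; the first rule is the one reported, and the other is given beside it. For distance the rule set in advance was met, but the reading given is the more cautious one that follows from leaving out 2 genes, which was added once values were known. The test of narrow coverage range next to snoRNA genes replaced a count of calls, which had argued against it, once that count was known, since called genes could hardly have lost their call; the new one leaves it open. The genes below were listed because the difference between the mutants itself passed limma's test; YMR194C-A, YKL102C and YDR269C, outside the rule for named genes here, were chosen after their values were seen.

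Pcf11-DNL minus Pcf11-13 Pol II was -2.34 for PCF11, -0.80 for PAM16, -0.78 for YMR194C-A, -0.69 for HIS4, -0.63 for VMA9, -0.55 for YKL102C and -0.53 for MIN3 on the log2 scale. It was 0.59 for YDR269C, 0.80 for HXT1, 0.95 for TOA2 and 1.09 for SPS4. At TOA2 the input differed by 0.88, leaving 0.07.

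Pol II over genes on the 3' side of snoRNA genes was higher in Pcf11-13, with a median of 0.27 over 49 genes and 12 called. DNA copy number is argued against by a median input change of 0.00 over the called genes, whose median Pol II change was 0.77, whereas the narrow coverage range may account for part, as the median of the 49 genes was 0.16 without both such libraries and 0.20 after quantile normalization (permutation p = 2.0e-05 in each, the smallest possible). Position next to any short noncoding gene was left undecided. Genes on the 5' side, with a median of 0.04, lay at percentile 97.4 of random sets (permutation p = 0.052, adjusted p = 0.065), where the bounds set for and against it overlap. Genes beside tRNA genes, with a median of -0.03 and 1 of 226 called, lay at percentile 8.5. No rise was thus seen beside tRNA genes, and what stays open is the 5' side of snoRNA genes. A test added afterwards put the 3' side above the 5' side by 0.23 (permutation p = 1.0e-05, the smallest possible). The sides were not matched for distance, as most 5' side genes lie farther off than the 3' side median gap of 229 bp. The difference can therefore not be assigned to side alone. Pol II running past the 3' end of snoRNA genes may contribute: genes on the opposite strand, which such a polymerase would enter in antisense, had a median of 0.37 (permutation p = 2.0e-05 against random gene sets, the smallest possible). The permutation tests here take genes as independent, so their p-values do not cover the spread between cultures. In Pcf11-DNL the comparison with random sets also passed a median of 0.02 beside tRNA genes (adjusted p = 0.015). Change fell with the gap (rho = -0.29, p = 0.047, and r = -0.28, p = 0.048, permutation tests over 49 genes), which meets the rule set in advance, but without the 2 genes farthest from the median gap rho was -0.21 (p = 0.16) and r -0.19 (p = 0.19), so the test does not pass without those genes and the relation is left undecided.

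Pol II over PCF11 was higher in Pcf11-13. DNA copy number alone is argued against by a Pol II change of 1.75 (SE 0.10) after the input change was subtracted. A loss of attenuation of equal size at all attenuated genes is argued against too, since the corrected PCF11 change exceeded that of URA2, the largest other, by 0.76 (SE 0.16); a looser rule, tried afterwards, left it undecided because 9 of 9 other attenuated genes were higher. A plasmid construct that differs in Pcf11-13 could also raise Pol II there, as 5 genes besides PCF11, LEU2 and TRP1 (MHF1, NFS1, NTH1, TSC13 and YDR008C, named after their values were seen) were over-represented in its input, although NFS1 lies next to LEU2 and YDR008C, by its systematic name, next to TRP1, so these may go with the LEU2 and TRP1 rises. MHF1 (input at 1.58 times the median gene, against 1.07 in WT) instead lies past the end of ADH1, not on its promoter side. TSC13 (1.44 against 1.07) lies ahead of the start of NOP1, on its promoter side. ADH1 and NOP1, named after their values were seen, had WT Pol II at 18.9 and 5.97 times the median gene. Their own input changed by 0.14 and 0.02 on the log2 scale in Pcf11-13 and was not called. A construct difference cannot be told apart from an effect of the allele, because construct and allele coincide. Whether PCF11 is attenuated on these plasmids was not tested.

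Gene lists in Pcf11-DNL moved together, 7 of the 12 called ones against their WT enrichment. The narrow coverage range of WT replicate 1 and Pcf11-DNL replicate 2 may account for part of this, but the tests leave it open: 2 of the 7 lists were still called after quantile normalization, and 7 of 7 without both libraries, where the remaining WT and Pcf11-DNL libraries still differ in range (SD 1.203 and 1.088). For the other 5 lists it is open as well, since 4 were still called after quantile normalization but 1 without both libraries. When lists were instead grouped by a WT enrichment above 2 on the log2 scale, a grouping picked after those counts were seen, 0 of 3 were still called; this grouping carries no weight of its own. An effect of the allele was not separated from the range of these libraries.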

How the results depend on the processing

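Quantile normalization, the pseudocount of 5, leaving out both libraries of narrow range, the crossed block and the list tests under library totals and meiosis gene scaling were chosen only after the data were seen. The planned count tests were not run, because the values are not counts. Where a group was left with 1 library, that library was assumed to vary like the others. The cause was not tested for any change below, and the unknown number of reads leaves counting error unmeasured.

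For Pcf11-13 against WT the 76 calls became 292 with library totals, 19 with meiosis gene scaling (14 higher and 5 lower), 44 without a filter, 256 at a mean coverage of at least 50, 139 with input as offset, 19 in the 12-library model, 232 with the 4 compared libraries, 269 after quantile normalization, 630 without both libraries of narrow range and 8 to 1213 with 1 library left out. All 76 kept their sign in each of these. For Pcf11-DNL against WT the 1 call became 8, 0, 1, 3, 2, 0, 0, 1, 110 and 0 to 401 in the same order. For Pcf11-DNL against Pcf11-13 the 11 calls became 119 (20 higher and 99 lower), 29 (21 higher and 8 lower), 10, 70, 13, 1, 702, 5, 411 and 1 to 679. Meiosis gene scaling moved the median of all genes to 0.15 in the first and to -0.23 in the last.

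Same-numbered libraries did not deviate in the same direction, so no pairing by number was seen in these values. Whether same-numbered cultures were handled together cannot be read from them. The r was -0.09 for WT and Pcf11-13, -0.89 for WT and Pcf11-DNL, and -0.07 for the mutants. The -0.89 means that libraries deviated together across the numbers, WT replicate 1 with Pcf11-DNL replicate 2, the libraries of narrow range. The replicate block gave 107, 3 and 20 calls in Pol II, 16 and 0 in input, and 11 and 13 lists. The crossed block gave 1 call for Pcf11-DNL against WT.

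Called lists numbered 0 for both mutants with an estimated correlation and 0 with fry. In Pcf11-13 they numbered 18 without both libraries of narrow range and 8 to 17 with 1 library left out, and in Pcf11-DNL 7 to 14. The correlation of the mutants was 0.76 over called genes, 0.37 after quantile normalization and -0.24 to 0.85 with 1 library left out. None of these has a simulated no-effect value of its own, so they cannot be read as likeness of the alleles. Sharing WT alone gave 0.48 over all genes in the main setting (highest 0.78). The input calls stayed at 15 to 18 and 0, and WT enrichment at 769 to 993 genes. PCF11 input was 2.24 and 2.14 times the median gene in Pcf11-13 replicates 1 and 2. Chromosome XIII input was 0.127 and 0.028 above WT in them on the log2 scale, so that value depends on the library kept.

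In Pcf11-13 without both libraries of narrow range, list medians turned to 0.18 (a-cell specific), 0.10 (glucose-repressed), -0.19 (glycolysis and fermentation), 0.17 (meiosis and sporulation), -0.30 (phosphate regulon) and 0.05 (subtelomeric). With 1 library left out, Pcf11-13 medians ran from -0.16 to 0.09 (glucose-repressed), -0.20 to 0.30 (glycolysis and fermentation), -0.57 to 0.16 (meiosis and sporulation), -0.31 to 0.41 (phosphate regulon), -0.24 to 0.11 (ribosomal protein), -0.12 to -0.00 (ribosome biogenesis) and -0.12 to 0.04 (subtelomeric). Pcf11-DNL medians ran from -0.21 to 0.62 (a-cell specific), -0.22 to 0.08 (cell wall), -0.07 to 0.07 (downstream of snoRNA), -0.11 to 0.22 (glucose-repressed), -0.40 to 0.09 (glycolysis and fermentation), -0.38 to 0.04 (histone), -0.25 to 0.46 (meiosis and sporulation), -0.53 to 0.05 (phosphate regulon), -0.02 to 0.10 (proteasome), -0.33 to 0.04 (ribosomal protein), -0.08 to 0.04 (ribosome biogenesis), -0.05 to 0.13 (stress response induced), -0.07 to 0.17 (subtelomeric) and -0.18 to 0.05 (tricarboxylic acid cycle and respiration).

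Named genes gave 547 results on the same side of the threshold, 17 that passed it and 59 that no longer did under other settings, and 244, 14 and 48 with 1 library left out, with 0 reversed. Without either Pcf11-13 library most named calls were lost, URA2 at adjusted p = 0.16 and 0.081. Lists gave 393, 19 and 62 under other settings with 6 reversed, and 224, 24 and 13 with 1 library left out with 27 reversed.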

Other observations

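The gene sets and genes here were chosen after the Pcf11-13 result was seen. Next to snoRNA genes, Pol II was also higher over genes that face them from the opposite strand, and 5 of 26 such genes were called in Pcf11-13: PAM16 beside SNR37, VMA9 beside SNR43, SSO2 beside SNR83, KTR2 beside SNR42 and DAS1 beside SNR128. The VMA9 value covers a short stretch of the gene only, and its gap to SNR43 is taken from the end of the whole gene. On the same strand 7 of 23 were called, with a median of 0.08 (permutation p = 0.013 against random gene sets, adjusted p = 0.022 over 10 comparisons). Of 226 genes on the 3' side of tRNA genes 1 was called and the median was -0.03 (adjusted p = 0.19). The comparisons with random sets take genes as independent, so their p-values do not cover the spread between cultures.

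In Pcf11-DNL, 0 of these genes were called by limma, which called 1 gene in all, with 107 at an unadjusted p under 0.05. The median was 0.06 over the 49 genes on the 3' side (adjusted p = 1.3e-04), 0.08 on the opposite strand (adjusted p = 2.5e-04) and -0.02 on the same strand (adjusted p = 0.4). It was -0.03 on the 5' side (adjusted p = 0.033) and 0.02 beside tRNA genes (adjusted p = 0.015), so small shifts also passed in sets not next to a snoRNA 3' end.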
